A study of Mus musculus with 2 samples.

How the data were processed

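RNA-seq libraries from the livers of 2 newborn mice were analysed from the deposited tables of genes and transcripts, 1 pair of tables per library. Per the labels' protocols, RNA was extracted with a mirVana kit and libraries followed a SmartSeq protocol, a method that amplifies cDNA by PCR before sequencing. No molecular identifiers appear in the tables. Per the deposited notes that accompany each library, values refer to the mm10 assembly with GENCODE M4 genes and were derived from a transcriptome alignment of the same library. The aligner and the quantification program are not given in the sources used here, and the column names are those RSEM writes.

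The authors deposited expected counts, which are estimated reads per feature with reads of several origins divided among them, so they need not be whole. The deposited TPM values are corrected for effective length and sum to 1000000 over all listed features, spike-ins included. The deposited FPKM values are a constant multiple of TPM within a library. The deposited posterior mean TPM and credibility bounds, treated as a score, are further estimates of the same quantity; the bounds were not used. The deposited isoform percent gives each transcript's TPM as a percent of its gene. Effective length was 99 nt below the listed length, so transcripts near that length get inflated TPM. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and near-identical copies share reads by estimation.

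The tables list 69691 features: 43346 genes, 26248 tRNA features and the spike-ins (96 ERCC RNAs and 1 phiX174 sequence). Gene names, types and coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10, by gene identifier without version; 42462 identifiers (98.0%) matched and 884 did not. Of 706 gene list symbols, 5 matched no gene and 1 matched through an older symbol. Total expected counts were 56959836 (pup 1) and 35973980 (pup 3), of which 54817565 and 34792898 were endogenous. A count of 0 then allows up to 0.0547 and 0.0862 CPM, respectively (3 counts per library).

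Spike-ins were removed and TPM was rescaled to 1000000 over endogenous features. A gene was called detected at 1 TPM or more. Log values are log2(TPM + 1), which understates differences of low genes, and agreement, spread and list shifts used genes with a mean expected count of at least 10. Both libraries belong to 1 group, so results are levels, mean ± SD (n = 2), and descriptive ratios of pup 3 over pup 1, and no count model was used for testing. A list's median log2 ratio was placed among 10000 random lists of equal size matched in 20 bins of mean expression, and called outside when beyond the 2.5 or 97.5 percentile. Gene lists (38), main thresholds, the rule for naming genes and the alternatives were fixed before the data were examined. The edges of abundance bins, the shares missing from the other library and the limits used to call an alternative moved were set afterwards. That rule took the 15 genes of highest mean TPM other than mitochondrially encoded ones, up to 4 leading members per list, the 5 largest ratios each way among genes with at least 100 expected counts in both libraries, the 3 genes per library with most counts and 0 in the other, all sex-linked genes, and the isoforms of Igf2, Hnf4a, Fn1, Pkm, Apob and Afp. Of the genes it took, some leading members are given only within their list's sum, and some are not reported here. Meg3, Neat1, Gm22133, Gm28661 and Gm29216 lie outside the rule and were chosen after their values were seen.

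The list procedure was tested on simulated Poisson counts for pup 3 against pup 1 over 8120 genes, 200 of them doubled or halved. Among the 83 changed genes of at least 30 TPM, median log2 ratios of 0.99 and -0.99 were recovered, and 6% of 100 random unchanged lists fell outside the central 95%. Poisson counting gives a median SD of 0.04 at 100 to 1000 expected counts, where the libraries had 2.37. The simulation also lacks genes lost from 1 library. It checks the arithmetic of the procedure, not its error rate in these data. Alternatives covered other units, thresholds, pseudocounts, filters, thinning of the deeper library, protein-coding genes only, each library alone, and scaling by edgeR TMM factors, DESeq2 size factors (both on rounded expected counts) and spike-in totals. Expression trends on length and GC content were fitted by lowess (fraction 0.3). Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.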

Results

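The data describe the liver of newborn mice of the B6NCrl strain, taken on postnatal day 0, when the organ holds both hepatocytes and blood-forming cells. RNA was measured in 2 libraries, from the liver of pup 1 (replicate 1) and the liver of pup 3 (replicate 2). Per the labels, each library started from 13 pg of total RNA longer than 200 nt, the amount of 1 cell-equivalent, with spike-in RNAs added. The material was tissue RNA at a single-cell amount, so each value is an average over the liver's cells. The labels describe 2 single livers but give both the same donor entry, so the spread between the libraries holds animal and technical differences that cannot be separated for endogenous genes. The tables summed to 56959836 expected counts for pup 1 and 35973980 for pup 3. The labels give 1 group and no contrast, so levels and their spread (mean ± SD, n = 2 throughout unless stated) are given, with no test between conditions.

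Transcripts of secreted hepatocyte proteins and of globins led the newborn liver. Trf, which encodes the iron carrier transferrin (chromosome 9, 103204001 to 103230444 in GRCm38), stood at 53244 ± 15557 TPM. Ahsg (fetuin-A) stood at 27042 ± 7281 TPM, albumin (Alb, chromosome 5, 90460897 to 90476602) at 16014 ± 2073 TPM and alpha-fetoprotein (Afp), the fetal counterpart of albumin, at 12811 ± 1108 TPM. The alpha-globin gene Hba-a2 (chromosome 11, 32296489 to 32297298) reached 59246 ± 10377 TPM, Hbb-bs 33605 ± 7406 TPM, Hba-a1 28159 ± 2993 TPM and Hbb-bt 26091 ± 808 TPM. The listed secreted plasma proteins held 16.2 ± 2.79% of endogenous TPM, with 23 of 25 genes at 1 TPM or more in both libraries. Globins and red cell membrane genes held 14.99 ± 2.12%, of which the 4 adult globin genes made up 14.7 ± 2.16%. Near-identical copies divide reads by estimation, so the split between Hba-a1 and Hba-a2, between Hbb-bs and Hbb-bt, and among the 5 Serpina1 genes (Serpina1e 9453 ± 5463 TPM) is uncertain.

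Lipid carriers and clotting factors followed. The apolipoprotein list held 6.52 ± 0.341% of TPM with all 15 genes detected in both libraries. Apoa1, the main protein of high-density lipoprotein, stood at 25381 ± 656 TPM, Apoe at 13047 ± 134 TPM and Apoa2 at 12610 ± 1813 TPM. Coagulation and complement genes held 3.09 ± 0.393%, led by the fibrinogen chains Fgg (7447 ± 2268 TPM), Fga (6269 ± 68.5 TPM) and Fgb (6177 ± 1445 TPM). The acute phase list held 2.79 ± 0.440%, largely the same fibrinogen genes, and 7 of its 15 genes were under 1 TPM in both libraries. Fetal and imprinted genes held 4.22 ± 0.659%. That list shares Ahsg and Afp with the secreted proteins, and its next members were the imprinted H19 (994 ± 279 TPM) and Igf2 (643 ± 46.1 TPM).

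Genes of the birth-time switch in fuel use were present at high levels. Fabp1, a fatty acid carrier, stood at 3310 ± 122 TPM. The fatty acid oxidation and ketogenesis list held 1.04 ± 0.0950% of TPM. In the list of gluconeogenesis and perinatal glucose metabolism (0.947 ± 0.0272%), Fbp1 stood at 3013 ± 563 TPM, Igfbp1 at 2805 ± 206 TPM, Pck1 at 774 ± 9.91 TPM and G6pc at 551 ± 98.1 TPM. Urea cycle and amino acid catabolism genes held 0.630 ± 0.00115%, led by Ass1 at 1794 ± 684 TPM and Arg1 at 1106 ± 827 TPM. The steadiness of that sum hides members that differed in opposite directions. Ass1 had 2277 TPM in pup 1 and 1310 in pup 3, whereas Arg1 had 521 and 1690 TPM.

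Genes of the adult liver list were sparse. Of the 16 adult liver genes, 12 were under 1 TPM in both libraries, and the list held 0.138 ± 0.0411%. Cyp2e1 stood at 607 ± 394 TPM and Cyp8b1, an enzyme of bile acid synthesis, at 396 ± 77.1 TPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 38.7 TPM in pup 3 and no counts in pup 1. Drug-metabolizing cytochromes P450 held 0.342 ± 0.0745%, led by Cyp3a11 at 737 ± 246 TPM, with 12 of 19 genes detected in both libraries. Bile acid synthesis and transport genes held 0.180 ± 0.0119%, led by the uptake carrier Slc10a1 at 726 ± 273 TPM, with 7 of 13 detected in both. Lipogenesis and cholesterol synthesis genes held 0.0435 ± 0.00154%, led by Fdps at 134 ± 71.2 TPM. Transcription factors of the hepatocyte held 0.0258 ± 0.000221%. Of these 17 genes, 3 reached 1 TPM in both libraries, 7 in 1 library and 7 in neither. Ppara had 29.0 TPM in pup 1 and 244 TPM in pup 3, and Nr1i3 had 116 and 8.69 TPM.

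Transcripts of blood-forming and immune cells were found, those of the rarer types in few genes. Heme synthesis and iron uptake genes held 1.27 ± 0.0480%, of which the ferritin genes Ftl1 and Fth1, also expressed by hepatocytes and counted again under metal storage below, made up 1.01 ± 0.0225%. The other 15 held 0.259 ± 0.0254%, with Alas2, the erythroid enzyme that starts heme synthesis, at 570 ± 102 TPM. Erythroid regulators held 0.118 ± 0.00690%, led by Bnip3l at 623 ± 86.5 TPM. The share rests largely on that gene, and 8 of the 18 genes were detected in both libraries. Neutrophil and granulocyte precursor genes held 0.815 ± 0.214%, with the calprotectin genes S100a8 at 3149 ± 1538 TPM and S100a9 at 1868 ± 843 TPM, and the granule gene Ngp at 1278 ± 399 TPM. Macrophage and Kupffer cell genes held 0.163 ± 0.0628%, led by Tyrobp (252 ± 129 TPM), C1qb (242 ± 24.2 TPM) and the Kupffer cell lectin Clec4f (175 ± 27.8 TPM). The platelet chemokine Pf4 stood at 675 ± 136 TPM, and its megakaryocyte and platelet list held 0.0965 ± 0.0354%. B lymphocyte genes held 0.0239 ± 0.0144%, led by Vpreb3 at 70.7 ± 63.6 TPM and Ighm at 50.7 ± 11.5 TPM. T and natural killer cell genes held 0.0101 ± 0.00481%, with Gzma at 64.4 ± 30.8 TPM. The mast cell and basophil list held 0.00239 ± 0.00325%, nearly all from Prss34 at 45.9 TPM in pup 1. Detected in both libraries were 3 of 13 megakaryocyte, 4 of 15 B lymphocyte, 1 of 14 T and natural killer cell and 0 of 10 mast cell genes.

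Markers of the other resident cells were low and often present in a single library. Of all features detected in either library 46.3% were detected in both, so this patchiness is not particular to these cells or to the lists above. Stellate and mesenchymal genes held 0.0537 ± 0.00303%, led by Dcn at 177 ± 52.9 TPM, with 5 of 19 genes detected in both libraries. Sinusoidal and vascular endothelial genes held 0.0442 ± 0.0156%, led by Egfl7 at 86.1 ± 4.65 TPM, and 11 of 19 were detected in 1 library. In the mesothelium list (0.0510 ± 0.0176%), most came from the keratin genes Krt18 (340 ± 10.4 TPM) and Krt8 (302 TPM in pup 3 and no counts in pup 1), which hepatocytes also express. Of its other members, Upk3b had 38.1 TPM in pup 1 and Msln 1 expected count, so the share does not measure mesothelium. Bile duct genes held 0.0206 ± 0.00896%, led by Spp1 at 167 ± 75.8 TPM, and 1 of 14 genes was detected in both libraries. Krt19 had no counts in pup 1, and Sox9 and Tspan8 none in pup 3, so the share rests mainly on Spp1. Of 28 genes of other tissues, 25 were under 1 TPM in both libraries, and Fabp2 was the most abundant at 56.4 ± 3.66 TPM.

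General cell functions spanned a wide range. Mitochondrially encoded genes held 3.95 ± 0.437%, led by mt-Atp6 at 9944 ± 1339 TPM, and 3 nuclear pseudogene copies that can share their reads (Gm28437, Gm28661 and Gm29216) held another 1.68 ± 0.383%. Cytosolic ribosomal protein genes held 2.32 ± 0.610%, led by Rps18 at 1938 ± 509 TPM. Iron and metal storage genes held 1.68 ± 0.117%, with the ferritin chains Ftl1 at 5138 ± 660 TPM and Fth1 at 4938 ± 435 TPM. Nuclear-encoded oxidative phosphorylation genes held 1.24 ± 0.271%, led by Atp5b at 995 ± 637 TPM. Growth factor signalling genes held 0.441 ± 0.00879%, histone genes 0.402 ± 0.120%, immediate early and stress genes 0.307 ± 0.00347% and cell cycle genes 0.270 ± 0.00266%. Leading members were Igfbp1, Hist1h2ap (1110 ± 826 TPM), Hspa8 (1353 ± 634 TPM) and Stmn1 (291 ± 199 TPM). The 10 most abundant genes of each library took 29.6 ± 0.0470% of TPM, with 8 shared, and the top 100 took 57.0 ± 2.24%, with 79 shared. The rRNA-overlapping gene Gm42418 held 1.37% in pup 1 and 0.331% in pup 3, and the very short Gm22133 (0.543 ± 0.109%) has a TPM inflated by its small effective length.

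**Figure D1:**
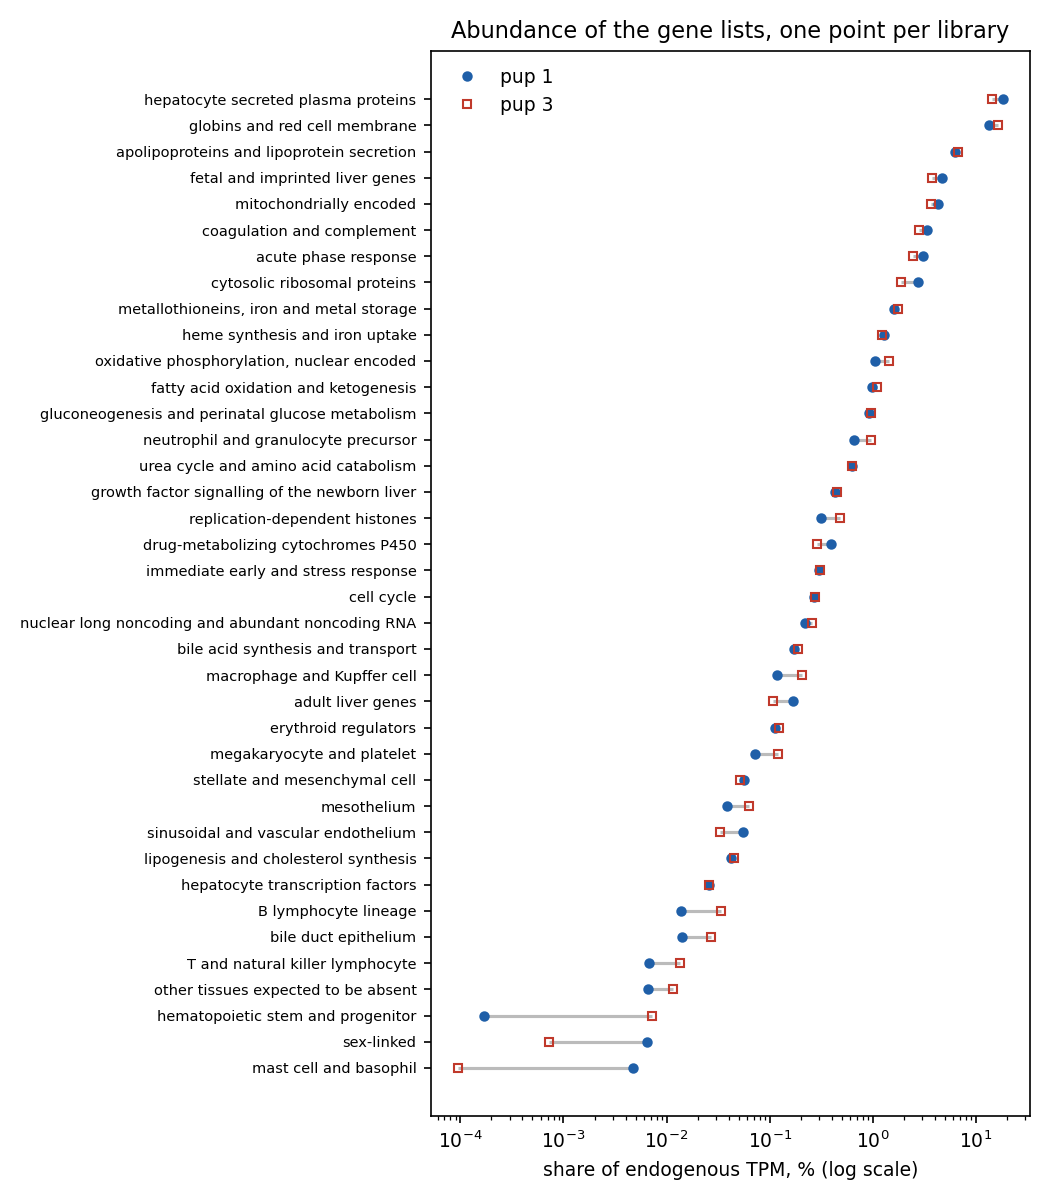
Share of endogenous TPM held by each gene list, in percent on a log axis, with a filled circle for pup 1 and an open square for pup 3; grey lines join the 2 libraries. Secreted plasma proteins (16.2%) and globins (14.99%) lead in both, and lists of rare cell types such as stem and progenitor cells lie farthest apart.

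How far detection repeated between the animals was examined next, because each library started from so little RNA. Abundant liver genes such as Trf, Alb and Apoa1 were found in both libraries, whereas many genes of middle abundance were heavily counted in one and never in the other. Ndufa10, a subunit gene of respiratory complex I (chromosome 1, 92439010 to 92473860), had 12604 expected counts in pup 1 and 0 in pup 3. Krt8 (chromosome 15, 101996698 to 102004482) had 14761 expected counts in pup 3 and 0 in pup 1. Against a floor of 3 counts per library, Ndufa10 was at least 2883-fold higher in pup 1 and Krt8 at least 7171-fold higher in pup 3. Rnf114 and Cdk5rap3 (13572 and 12644 expected counts) were counted only in pup 1, and Farsa and Flna (12176 and 12262 expected counts) only in pup 3. Floors and intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

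At 1 TPM or more, 5742 genes were detected in pup 1 and 5491 in pup 3. Of the 7678 detected in either, 3555 (46.3%) were detected in both, 2187 only in pup 1 and 1936 only in pup 3. Detection in both covered 29.0% of genes at a mean of 10 to 30 TPM, 75.7% at 30 to 100 TPM, 97.9% at 100 to 300 TPM and all 316 genes at 300 to 1000 TPM. Spike-in RNAs, which do not come from the animals, went missing too. Of the 5157 endogenous features at 10 to 100 TPM in either library, 52.4% (exact 95% interval 51.1 to 53.8%) were under 1 TPM in the other. For spike-ins the count was 11 of 19, or 57.9% (33.5 to 79.7%). Taken from pup 1 alone, 42.4% of such endogenous features and 6 of 12 spike-ins were missing from pup 3, and from pup 3 alone 40.8% and 5 of 13 were missing from pup 1. At 100 to 1000 TPM in either library, 9.98% (8.47 to 11.7%) of endogenous features and 0 of 11 spike-ins (upper bound 28.5%) were missing. Of the 96 ERCC spike-ins listed, 36 reached 1 TPM in pup 1 and 34 in pup 3, and spike-ins took 3.52 ± 0.338% of expected counts.

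**Figure D2:**
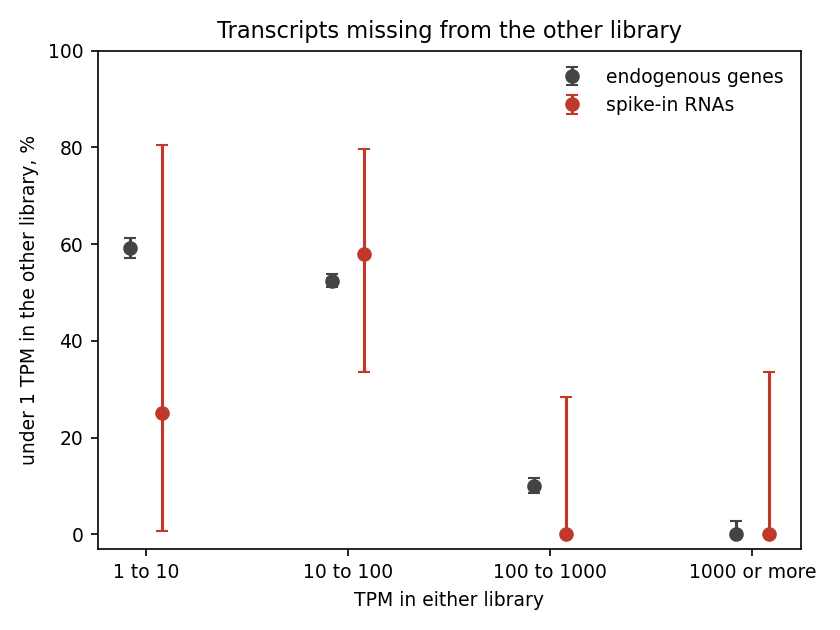
Percent of transcripts at a given TPM in either library that were under 1 TPM in the other, each counted once per range, for endogenous genes (dark) and spike-in RNAs (red), with exact 95% intervals as bars. At 10 to 100 TPM the shares were 52.4% and 57.9%.

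Across genes, the libraries were alike at the top and diverged below. The 103 genes with a mean of at least 1000 TPM, among them Trf, Hba-a2 and Fabp1, had a Pearson r of 0.88 and a Spearman rho of 0.80 on log2(TPM + 1). Over all 8120 genes with a mean expected count of at least 10, r was 0.36 and rho 0.29. Genes are not independent replicates, so these values describe the libraries only. The median SD of log2(TPM + 1) was 2.37 for genes with a mean of 100 to 1000 expected counts, where Poisson counting alone gave 0.04. It was 0.51 at 10 to 100 counts, where the value depends on the pseudocount (1.80 with log2(TPM + 0.1)), 1.67 at 1000 to 10000 counts, 0.40 at 10000 to 100000 and 0.20 above. Among spike-ins the medians were 3.48 at 100 to 1000 counts (17 spike-ins), 0.48 at 1000 to 10000 (9), 0.28 at 10000 to 100000 (10) and 0.30 above (4). At 1000 to 10000 counts the spike-ins thus spread less than the genes, but these bins match counts and not TPM. In pup 1, for example, ERCC-00060 had 5177 expected counts at 273 TPM and Abcb10 5393 at 30.7 TPM. The gap is therefore not read as a difference between the animals. Tfdp2, a partner of E2F transcription factors, had the largest ratio toward pup 3 among genes with at least 100 expected counts in both, with 0.407 TPM in pup 1 and 181 TPM in pup 3 (log2 ratio 7.02). Ap3m1 (6.24), Tsn (6.07), Myo10 (5.86) and Scpep1 (5.76) came next. Toward pup 1, Matr3, a nuclear matrix protein gene, had 187 and 2.62 TPM (-5.70), with Grb10 (-5.68), Cept1 (-5.62), Tut4 (-5.18) and Pros1 (-4.85) after it. A chi-square test of the counts of the 2 libraries gave 1793 per degree of freedom, so they are not one library deposited again.

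**Figure D3:**
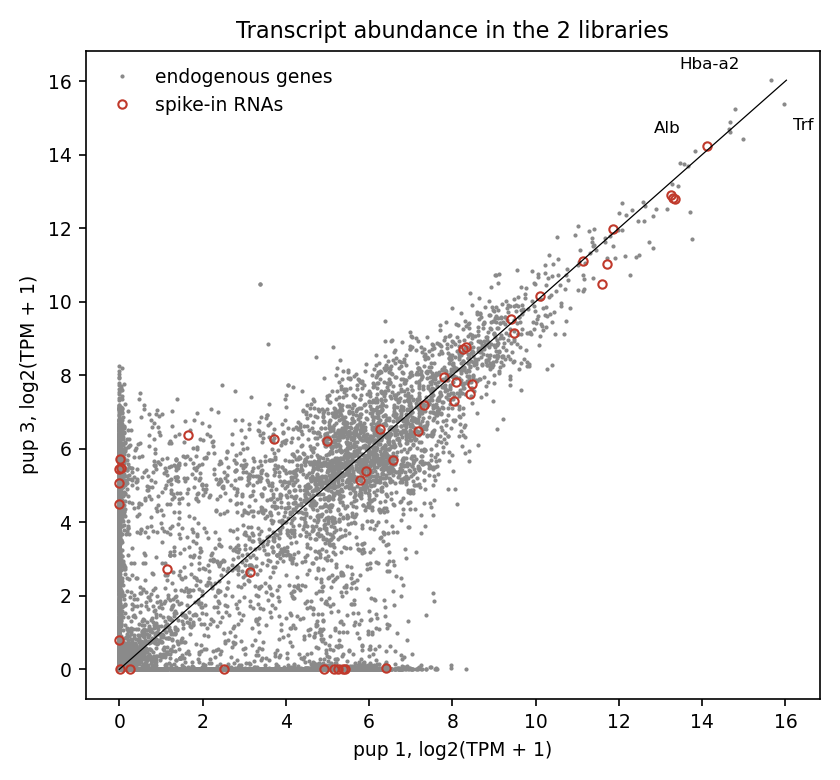
Abundance of each gene (grey) and spike-in RNA (red circles) as log2(TPM + 1) in pup 1 (x axis) and pup 3 (y axis), with the line of equality. Abundant genes such as Trf, Alb and Hba-a2 lie near the line, and points along both axes are transcripts found in a single library.

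Shifts of whole gene lists between the pups were described by their median log2 ratio (pup 3 over pup 1). Ribosomal protein genes were lower in pup 3 in 32 of 37 cases, with a list median of -0.52. Rps18 had 2298 TPM in pup 1 and 1578 in pup 3, Rps19 had 2076 and 1282, and Rps14 had 1389 and 846. That median lay at the 0.02 percentile of 10000 random lists matched on expression, whose central 95% ran from -0.23 to 0.38. Coagulation and complement genes had a median of -0.48 (percentile 2.04, 19 of 27 lower) and urea cycle genes one of -0.58 (percentile 2.21, 12 of 19 lower).

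In the other direction, nuclear and abundant noncoding RNAs had a median of 1.82 (percentile 99.7), which was 0.62 (percentile 89.3) and inside the range over the 6 members with at least 100 expected counts in both libraries. Malat1 had 342 TPM in pup 1 and 1210 in pup 3, Neat1 0.353 and 34.9, and Meg3 0.171 and 65.9. The summed share of the list differed little, at 0.221% in pup 1 and 0.255% in pup 3. The list was divided, with 5 of 9 members higher and H19, Gas5 and Rn7sk among those lower. Xist, treated below as a marker of sex, was among those higher. The median without Xist was not computed, so how far the call rests on it is not known. The 5 stem and progenitor genes tested had a median of 2.66 (percentile 97.8), with 3 of them at 0 counts in pup 1, and 5.54 with those at their bound. Meis1 had 1865 expected counts in pup 3 and 0 in pup 1, and Myb had 0.728 and 30.02 TPM. These were 5 of 37 lists outside the central 95%, where 1.85 would be outside by chance, and each pup is 1 library, so no p-value is given. Among 4 other filters and pseudocounts, the ribosomal list stayed outside under all, the coagulation and noncoding lists under 3 and the urea cycle list under 1, with each change of gene filter ending its call (percentiles 2.63 to 3.94). The stem and progenitor list, too small for 1 of them, did so under 1 of 3. Scalings of whole libraries are left out of these tallies, since 1 factor per library moves a list against random lists only through the pseudocount. That effect was not always small. The neutrophil list went from percentile 67.9 to 79.4 with TMM factors and to 55.9 with spike-in totals.

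**Figure D4:**
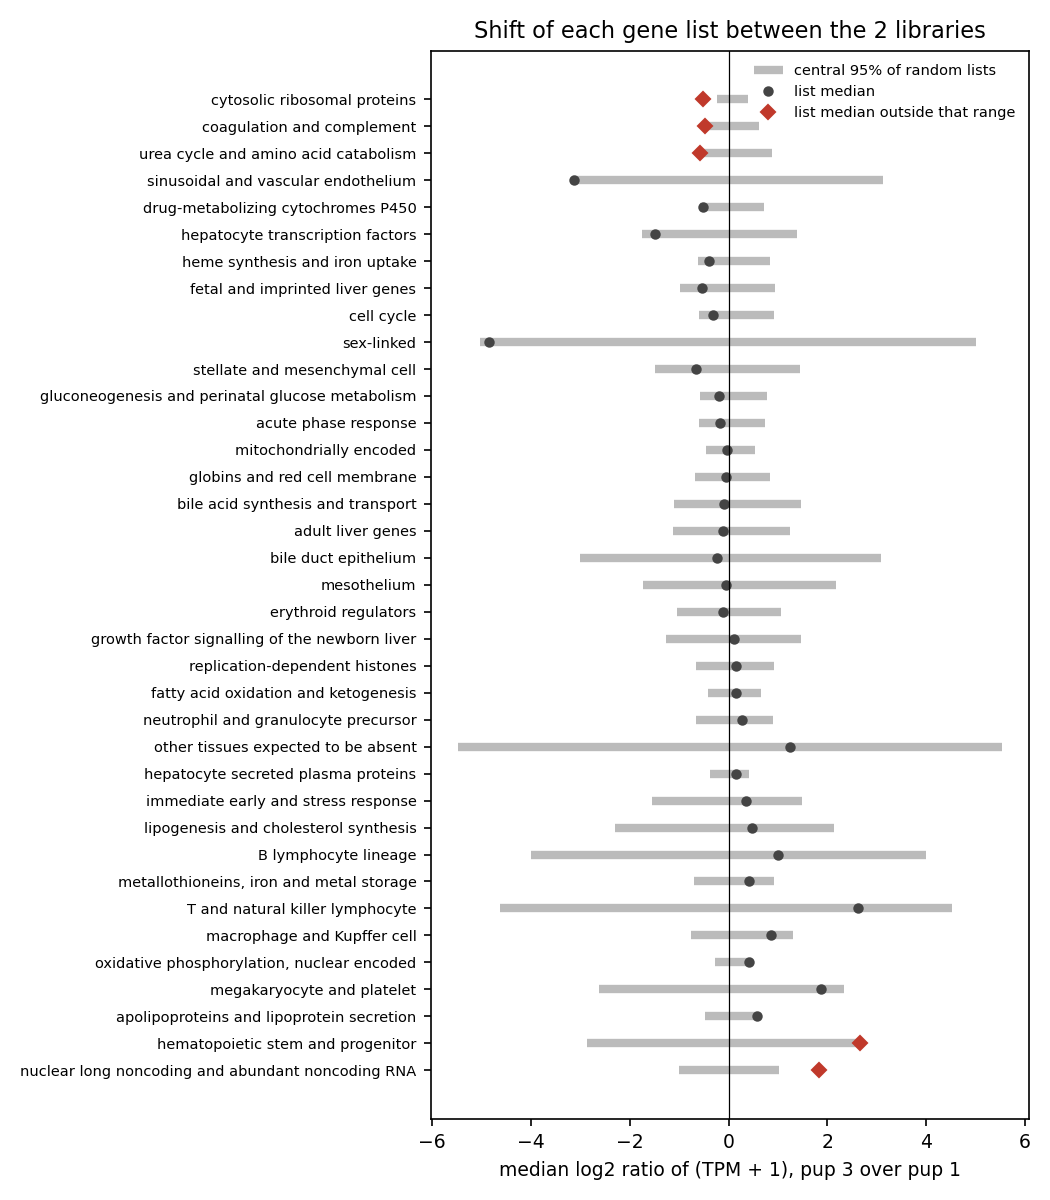
Median log2 ratio of (TPM + 1), pup 3 over pup 1, for each gene list (points), with the central 95% of matched random lists as grey bars; red diamonds mark the 5 medians outside their bar. Ribosomal proteins (-0.52) and noncoding RNAs (1.82) lie clear of their bars, and the other 3 lie at the edge.

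For the remaining lists the median lay within the range of random lists. The apolipoprotein list (0.57, percentile 97.4) and the endothelial list (-3.14, percentile 2.62) were near its ends, and lay outside under 2 and 1 of the 4 other filters and pseudocounts. The hepatocyte transcription factor, megakaryocyte and lipogenesis lists each lay outside under 1 of 4, and the sex-linked list under 1 of 3. With TMM or DESeq2 factors the endothelial list was outside as well (percentile 2.4). The endothelial median was -0.11 over the 5 members with at least 100 expected counts in both libraries. Median and mean differed in sign in 8 lists. For secreted plasma proteins the median was 0.15 and the mean -0.07, while the summed share was 18.2% in pup 1 and 14.2% in pup 3. For globins and red cell membrane genes the median was -0.06, while the summed share was 13.5% and 16.49%. Scaling by TMM factors moved every gene by -0.26 and scaling by spike-in totals by 0.25 on the log2 scale. Medians nearer to 0 than these shifts, such as those of secreted proteins and globins, change sign with the scaling by construction, so no direction is read from them.

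The labels record the animals' sex as not collected. The Y-linked genes Eif2s3y (chromosome Y, 1010543 to 1028847) and Ddx3y had 37.2 and 27.7 TPM in pup 1 and no counts in pup 3. Kdm5d and Uty had 1 expected count each in pup 1. Xist, the RNA that coats the inactive X chromosome, had 7.21 TPM in pup 3 and 1.09 expected counts, listed at 0 TPM, in pup 1.

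The transcript tables allowed isoforms to be compared. Pkm was assigned wholly to 1 transcript, Pkm-201, in both libraries, and Afp has 1 listed transcript. Fn1 (fibronectin) had Fn1-216 at 33.6 ± 0.665% of the gene and the retained-intron form Fn1-202 at 38.6 ± 6.53%. Igf2-208 took 47.3 ± 2.84% of Igf2, while Igf2-203 had 15.6% in pup 1 and 36.5% in pup 3. The short Apob-204 took 57.6 ± 9.13% of Apob against 28.5 ± 10.6% for the full-length Apob-202. Apob-203 had 27.9% in pup 1 and 0% in pup 3. Short and incomplete transcript models gain TPM from few reads, so Apob-202 had 34284 and 69293 expected counts against 6149 and 9099 for Apob-204. Hnf4a was assigned 90.0% to Hnf4a-201 in pup 1 and 100% to Hnf4a-202 in pup 3. Those assignments rest on 551 and 556 expected counts. Genes with a mean of 100 to 1000 counts had a median SD of 2.37 between the libraries, so no isoform switch is read from them. Among 3124 genes with at least 2 listed transcripts, a mean of at least 100 expected counts and expression in both libraries, 63.6% (Wilson 95% interval 61.9 to 65.2%) had the same most abundant transcript, against 23.4% after shuffling transcripts within genes.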

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

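The added settings (at least 20 TPM for detection, 100 expected counts in both libraries for list shifts, 10000 counts for isoforms) were chosen after seeing the data. No paired analysis was possible because both libraries belong to 1 group. Causes of the changes below were not tested except where the setting itself shows them. With expected counts in place of TPM, which drops the length correction, secreted plasma proteins held 21.6%, globins and red cell membrane genes 6.46% and the top 100 genes 51.8%. Leaving out the 10 most abundant genes, which removes the main members, left these lists 7.49% and 0.400%. Spike-ins took 6.12% of TPM. Genes detected in both libraries numbered 5474 at an expected count of at least 1 and 2306 at 20 TPM. Each library alone gave 5491 to 5742. Agreement across genes (r = 0.36) was 0.16 with log2(TPM + 0.1), 0.61 with log2(TPM + 10), 0.53 with no filter, 0.26 at a mean of at least 100 expected counts and 0.24 on CPM, so this value is largely set by how low genes enter. The median spread moved most with log2(TPM + 0.1), from 0.51 to 1.80 at 10 to 100 counts and from 2.37 to 4.45 at 100 to 1000 counts. With TMM factors it was 0.46 at 10000 to 100000 counts and 0.25 above, and DESeq2 size factors gave 0.46 and 0.25. Lists outside the central 95% numbered 3 when genes needed 100 expected counts in both libraries. Of the 5 lists called before, 1 (ribosomal proteins) was among them, with apolipoproteins (0.57, percentile 98.9) and lipogenesis (1.49, percentile 98.2). The noncoding RNA list (0.62), coagulation and urea cycle genes were inside their ranges, and the stem and progenitor list had too few members. One scaling factor per library cannot move a list against random lists except through the pseudocount. The same most abundant isoform was found for 65.8% of genes at a mean of 1000 expected counts and 87.2% at 10000. Of all list shares, 95 moved by over 1 SD and 131 did not (each library alone is always within 1 SD of the mean of 2, which says nothing), and of list medians 23 moved by more than the SD of random lists and 230 did not. The largest group was 28 of 38 shares that were higher without the 10 most abundant genes. For a list holding none of those genes the rise follows from the smaller total, so it says nothing about the list. No called value reversed direction, which under the scalings follows from medians larger than the shift. Thinning pup 1 to the depth of pup 3 left 5318 genes counted in both, against 5482 without thinning.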

Other observations

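Tests of sampling, depth, animal differences, cell shares (with their values over genes counted in both libraries) and sex were chosen after the results were seen; those of length, GC content and pseudogenes were written down beforehand. The libraries held 1 group, so no biological explanation was tested by the design.

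Genes with at least 100 expected counts in one library and under 1 in the other numbered 1595 in pup 1 and 1180 in pup 3, among them Ndufa10 and Krt8. Depth as the cause is argued against by the shallower library, which held 42.5% of them. For the 1893 of these genes at 10 to 100 TPM, differences between the animals as the whole cause are argued against by the spike-ins, of which 11 of 19 at 10 to 100 TPM in either library went missing from the other (lower 95% bound 33.5%; 21.1% and 13.9% for levels taken in pup 1 or pup 3 alone). At a mean of 1000 to 10000 expected counts the 9 spike-ins spread less than endogenous genes (median SD 0.48 and 1.67). That comparison is matched on counts and not on TPM, so it does not bear on differences between the animals. Sampling of few RNA molecules before amplification remains a candidate explanation, since 57.9% of spike-ins and 52.4% of endogenous features went missing at 10 to 100 TPM. For the 73 genes at 100 to 1000 TPM, Ndufa10 and Krt8 included, both stay open, since 9.98% of endogenous features and 0 of 11 spike-ins (upper 95% bound 28.5%) went missing there, as do both for lower genes and for any single gene.

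Ribosomal protein transcripts were lower in pup 3 (median -0.52). After removal of the trend on transcript length the median was -0.62 (percentile 0.01), and after removal of that on GC content -0.37 (percentile 0.1). With trends fitted over genes counted in both libraries the medians were -0.69 and -0.57. Those trends were weak (Spearman rho -0.042 and -0.019), so their removal could change little. A general trend on length or GC content may thus not be the whole cause, while a bias confined to some transcripts was not tested. Adding 86 pseudogenes named for a member left -0.48 (percentile 0.035), and all processed pseudogenes together were 0.0190 points of TPM higher in pup 3 where ribosomal genes were 0.863 points lower. RNA handling, amplification and a difference between the animals stay open and untested.

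The summed share of adult globins was higher in pup 3 and that of secreted plasma proteins lower (18.2% and 14.2%), within what 2 libraries can show. A larger erythroid share would raise other erythroid genes as well. In these libraries 46 of them had a median log2 ratio of -0.31 (bootstrap standard error 0.21, with 19 higher and 27 lower) against a globin median of 0.29. Over the 34 with at least 100 expected counts in both libraries the median was -0.18 (0.18), although the 7 erythroid regulators among them had 0.28 (1.69). As a set they did not rise with the globins. Standard errors here come from redrawing genes, so they hold no spread between libraries, and the globin median has none. The erythroid share is therefore not decided. A smaller hepatocyte share as the whole cause would lower all hepatocyte genes by about the -0.35 of the secreted proteins' sum. The 99 genes of 5 other lists had a pooled median of -0.022 (0.10, with 49 higher and 50 lower), and 88 counted in both libraries 0.016 (0.10). The secreted proteins' own gene median was 0.15 (14 of 23 higher), so a sum and a gene median are unlike measures here. These values argue only against an equal fall of all hepatocyte genes. The lists were split, with apolipoproteins at 0.57 (0.23) and fatty acid oxidation at 0.15 (0.18) against coagulation at -0.48 (0.34), urea cycle at -0.58 (0.35) and glucose metabolism at -0.19 (0.44), so a fall confined to some lists, or to a few very abundant transcripts such as Trf and Serpina1e, stays open; ferritin and other erythroid members are also expressed by hepatocytes.

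A hypothesis on sex, which the labels do not record, is that pup 1 was male and pup 3 female. In pup 1, 3 genes of the Y chromosome had at least 100 expected counts (Ddx3y 4869, Eif2s3y 2696 and the pseudogene Gm20775 321), which goes with pup 1 being male. The sex of pup 3 stays open. No Y-linked gene was counted there and Xist had 3649 expected counts. Of endogenous features at 10 to 100 TPM in pup 1, however, pup 3 lacked 42.4%. At that share a male library would lack both Eif2s3y and Ddx3y with a chance of 18.0%. That chance takes the losses as independent and leaves out Xist, a single gene counted with unknown strand.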
